A study of Homo sapiens with 12 samples.

How the data were processed

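The study measured N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, by immunoprecipitation followed by sequencing in HK2 cells, an immortalised human proximal tubule cell line. Fragmented poly(A) RNA was sequenced before (input) and after (IP) pull-down with an antibody against m6A. Per the labels there were 3 input and 3 IP libraries of control cells (NC), and 3 input and 3 IP libraries of cells overexpressing the m6A reader YTHDF1 (OE). The labels do not say whether the numbered libraries of a group came from separate cultures, so the spread between them, and every p-value resting on it, may be technical in part. A transfection text naming a YTHDF1 plasmid is shared by all samples, while the treatment field reads none in both groups, so the labels do not say what the NC cells received.

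The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for the 6 input libraries, which lists 29462 genes, each above 0 in at least 1 library. The authors also gave 1 m6A peak list per group with a log2 ratio of IP over input, a p-value and an adjusted p-value for each peak. A further deposited table gives log2 IP/input in OE and in NC, their difference and p-values for sites compared between the groups. Another deposited table joins these sites with the authors' own test of gene expression. The submitters' processing notes name fastp, FastQC, HISAT2, HOMER and StringTie with genome build hg38, without versions or roles. The peak caller and the tests behind the authors' p-values are not given in the sources used here. The lists hold peaks with an unadjusted p of up to 0.05 and a log2 ratio above 0, and the table of compared sites holds sites with an unadjusted p of up to 0.05, apart from 6 sites without a p. Starts in these tables are counted from 0, so 1 was added to each. The span of a peak runs from its first to its last base on the genome, introns included.

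Read counts were not used here, so the depth of the libraries is unknown, and no counting intervals are given for FPKM. The FPKM of the input libraries summed to between 197348 and 215381. No value per IP library was used, so the tests of IP enrichment per library and of the interaction between IP and group were not run. The search for the m6A sequence motif and the distance of peaks to the stop codon were not analysed here, since they need a genome sequence and a transcript annotation. Peak positions rest on the annotation column of the authors' tables.

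Genes with FPKM of at least 1 in at least 3 of the 6 input libraries were tested, on log2(FPKM + 1), with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). Adding 1 to FPKM makes log2 changes of genes with low expression smaller than their FPKM ratios. Means and SDs are over the 3 libraries of a group on the FPKM scale. YTHDF1 alone was also compared with an exact two-sided permutation test. The test was also run on simulated data with the spread of these libraries, where 50 of 12438 genes were changed at each size. It recovered 18% of genes changed by 0.32 log2 units, 68% at 0.58, 94% at 1 and 96% at 2. It made 7 false calls there (4.83% of calls), and 0 in data with no change. Far fewer genes were changed there than were called in the real data, so these rates need not hold for the real data. The code for overlaps and lists met 7 of 7 checks on simulated data.

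27 gene lists were fixed before the data were examined, as were the tests, their thresholds, the rule for naming genes and the alternatives, except where stated. They cover m6A writers, erasers and readers, m6A landmark transcripts, stress granule core, P-body and deadenylation, integrated stress response, unfolded protein response, cytosolic heat shock, tubular injury, NF-kB inflammatory genes, interferon-stimulated genes, apoptosis, p53 targets, cell cycle, oxidative stress and ferroptosis, hypoxia and glycolysis, EMT and fibrosis, translation initiation, cytosolic ribosomal proteins, mtDNA-encoded respiratory chain and replication-dependent histones. The remaining lists are markers of proximal tubule, distal nephron, fibroblasts, endothelium and leukocytes. The 21 lists with at least 5 tested genes were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Limma's fry tested whether the genes of a list moved, on balance, one way, which is not a comparison with other genes. After the data were examined, camera was also run over 1843 Gene Ontology terms that the expression table lists, each with 10 to 500 tested genes.

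The rule named YTHDF1, the 10 most raised and 10 most lowered called genes whose groups did not overlap and whose higher mean reached 1 FPKM, and up to 4 called members per list by size of change. From the site table it named the 10 called sites with the largest and the 10 with the smallest difference, 1 per gene. From each peak list it named the 5 genes with the smallest adjusted p, ties broken by the IP/input ratio, and up to 4 members each of the m6A and stress granule lists. From the joint table it named 3 genes per quadrant of the 2 changes. Not every gene that the rule names is given in the text. IFNB1, IFNL1, METTL3, METTL14, G3BP1, LUM, the ribosomal paralogs not called and FCER1G and PTPRC fall outside this rule and were chosen after their values were seen.

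Peaks of the groups were compared with bedtools 2.31.1 on the same strand, and counted as shared at a reciprocal overlap of at least 50%. Sites past the authors' adjusted p of 0.05 were counted by direction, and shares carry 95% Wilson intervals that treat sites as independent, which they are not. For each list, the share of genes with such a site was compared with that of all other genes with a peak by a two-sided Fisher's exact test, adjusted over the 22 lists with at least 5 such genes. The site with the largest absolute difference per gene was set against the input change by Spearman's rho across genes, and by Fisher's exact test on the 4 quadrants. The FPKM changes of genes with a peak in both lists were compared with those of genes with a peak in neither by camera, over all tested genes and in 10 bins of mean expression. Overlaps, counts and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

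The alternatives were a pseudocount of 0.1 or 0.5, no filter or a minimum of 5 FPKM, libraries centred on their median, quantile normalization, no trend, array weights, library numbers as a block, a minimum of 1.5-fold, and each input library left out in turn. For peaks and sites they were stricter thresholds, other overlaps, unadjusted p-values, other choices of the site per gene and higher expression. Chosen after the data were examined were leaving the interferon-stimulated genes out of the marked genes, removing a spline of mean expression, subtracting the median shift of shared peaks, and using called sites only. The authors' counts were set beside those made here.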

Results

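Gene expression was measured as FPKM in 6 input libraries of HK2 human renal tubular epithelial cells, 3 from control cells (NC) and 3 from cells overexpressing YTHDF1 (OE). YTHDF1 is a cytoplasmic protein that binds m6A-modified mRNA. The m6A measurements came as 1 peak list per group, made by the authors from the IP and input libraries. No spread between libraries is given for peaks, and how replicates entered the authors' p-values is unknown. The title of the series places the work in acute kidney injury and stress granules, and the labels describe untreated cells. Between 12122 and 12199 genes reached 1 FPKM in each NC library, and between 12415 and 12489 in each OE library. YTHDF1 took 0.0115% to 0.0133% of summed FPKM in the NC libraries and 0.681% to 0.962% in the OE libraries. Pairs of libraries within a group correlated at r = 0.984 to 0.989 across genes.

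The first comparison checked the overexpression itself. YTHDF1 (ENSG00000149658; chromosome 20, 63195429 to 63216139, minus strand) rose from 26.1 ± 1.65 FPKM in NC (SD, n = 3) to 1677 ± 279.5 FPKM in OE (SD, n = 3), a 64.3-fold higher mean. All 3 OE libraries lay above all 3 NC libraries. The log2 change was 5.94 with a standard error of 0.12 (limma, adjusted p = 1.56e-07). The exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 allows.

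The second comparison asked which transcripts differed between YTHDF1-overexpressing and control cells. Interferon-stimulated genes rose the most. IFI6 (ENSG00000126709; chromosome 1, 27666064 to 27672198) went from 19.0 ± 2.92 to 1085 ± 183 FPKM, and ISG15 (ENSG00000187608; chromosome 1, 1001138 to 1014540) from 12.9 ± 0.17 to 154 ± 45.2 FPKM (SD, n = 3 in each group). Transcripts of ribosomal proteins fell together, among them RPS3A (ENSG00000145425; chromosome 4, 151099624 to 151104642), which went from 386 ± 34.3 to 176 ± 9.44 FPKM, and RPL7 (ENSG00000147604; chromosome 8, 73290242 to 73295789), which went from 295 ± 21.8 to 144 ± 1.52 FPKM (SD, n = 3). Cell cycle genes such as KIF20A and MCM6 were lower, and the matricellular genes CCN1 and CCN2 were higher.

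Of 12438 genes tested by limma, 3958 passed an adjusted p of 0.05, 2323 higher and 1635 lower in OE, and 5462 had an unadjusted p under 0.05. Among the called genes, 398 were at least 1.5-fold higher and 244 at least 1.5-fold lower, and 102 and 38 changed at least 2-fold. The FPKM of the groups did not overlap for 5996 genes (48.2% of those tested), where chance gives 10%, and 3929 of the called genes were among them. The median log2 change of all tested genes was 0.042. The share of calls that were higher, 58.7%, depended on the scaling. It was 40.1% (1601 higher, 2387 lower) after centring each library on its median and 48.6% (1781 higher, 1886 lower) after quantile normalization. Without NC library 1 the calls numbered 2534, and without OE library 3 they numbered 2264. The authors' deposited test could be compared for 8269 genes, which had a listed site and were tested here. Of these, 2893 had q under 0.05, 1283 of them higher and 1610 lower. This split covers fewer genes than the 12438 above, so the 2 splits cannot be set directly against each other. The split of all genes called here among the 8269 was not counted. Among 2398 of them with a site past the authors' adjusted p of 0.05, 868 and 430 were higher in expression and 959 and 141 lower. The majority direction therefore need not be the same in the 2 tests. The authors marked 133 of the compared genes significant, 108 of them higher. Of the 2893 genes, 2417 were among the 2800 called here, all 2417 with the same sign.

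The 10 most raised genes were YTHDF1, IFI6, OAS2, IFI44, ISG15, IFITM1, IFI27, IFI44L, OAS1 and MX1, so that 9 of them were genes induced by interferon. IFI6 rose by 5.76 log2 units (adjusted p = 4.03e-07), IFI44 by 3.45 (adjusted p = 6.27e-06), ISG15 by 3.44 (adjusted p = 2.39e-05) and IFITM1 by 3.29 (adjusted p = 3.89e-06). OAS2 was near 0 in the NC libraries, at 0.026 ± 0.019 FPKM, and reached 14.4 ± 5.41 FPKM in OE (SD, n = 3). All 29 tested members of the interferon-stimulated list were called higher, 29 also when adjusted over the list alone, with a median log2 change of 1.97. The expression filter let in genes expressed in OE alone. Without a filter 30 of 35 members were called higher and 0 lower, and with any OE library left out 23 members were tested, all 23 higher. The list passed camera (adjusted p = 5.06e-26), but not with an estimated correlation (adjusted p = 0.303). The interferon genes IFNB1 and IFNL1, listed at 0 in NC, averaged 0.18 ± 0.11 and 0.34 ± 0.35 FPKM in OE (SD, n = 3) and were below the expression filter.

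**Figure D1:**
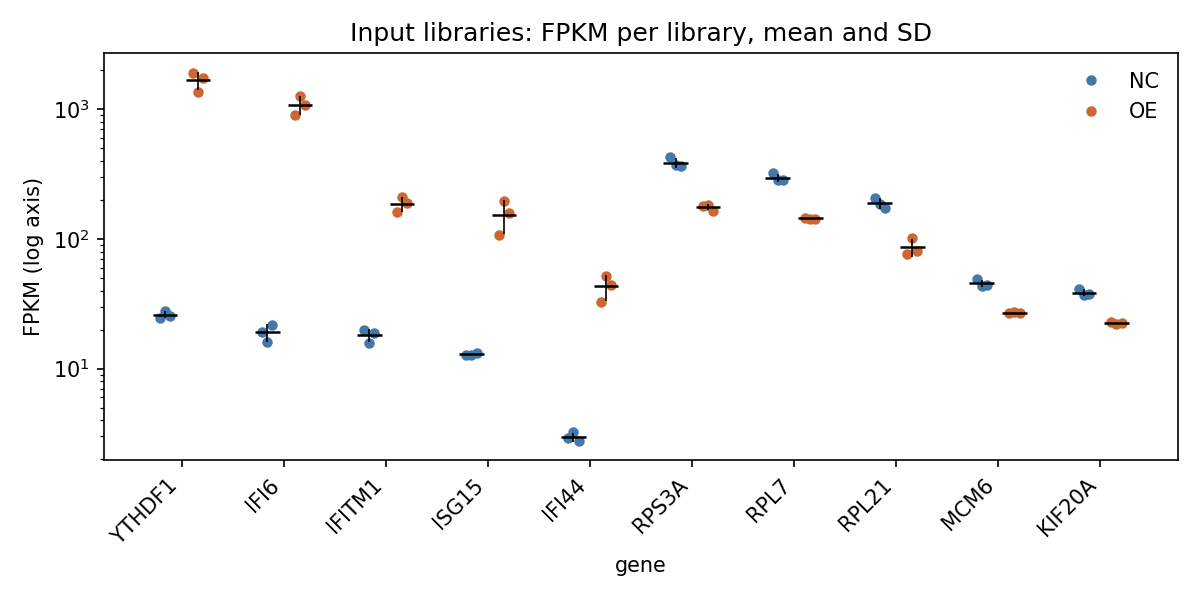
FPKM of 10 genes in each input library on a log axis, NC in blue and OE in orange, with the group mean (horizontal line) and SD (vertical line) of 3 libraries. YTHDF1 and the interferon-stimulated genes IFI6, IFITM1, ISG15 and IFI44 were higher in all 3 OE libraries, and RPS3A, RPL7, RPL21, MCM6 and KIF20A were lower in all 3.

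Among the fixed lists, that of cytosolic ribosomal proteins had the most genes called lower. Of 78 tested genes of cytosolic ribosomal proteins, 75 were called lower and 0 higher, and 76 were lower when adjusted over the list alone. The median log2 change was -0.75, and it was -0.83 after centring and -0.55 after quantile normalization. The 3 genes not called were the paralogs RPL7L1, RPL22L1 and RPS27L. RPL21 fell by 1.13 log2 units (adjusted p = 0.000498), RPS3A by a log2 change of -1.13 (adjusted p = 8.59e-05), RPL7 by -1.03 and RPL9 by -1.02. Genes of translation initiation followed the same direction, with 20 of 32 called lower and 2 higher (21 and 2 adjusted over the list alone), at a median of -0.30. EIF3L (-0.84), EIF4B (-0.71) and EIF3E (-0.67) were lower, while EIF2AK2, which encodes the interferon-induced kinase PKR, was higher by 1.44. Both lists passed camera (adjusted p = 3.98e-43 and 1.93e-08), and neither passed with an estimated correlation (adjusted p = 0.303 for each).

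The 10 most lowered genes were TOMM6, SNORD14E, SNORD125, MIR3142HG, MIR25, RPL21, RPS3A, RPSA, EEF1B2 and NME1. TOMM6 fell from 149 ± 23.8 to 33.7 ± 47.2 FPKM (SD, n = 3), with OE libraries at 9.25, 88.2 and 3.71 FPKM. Its log2 change of -3.19 lost the call without NC library 1, 2 or 3 or without OE library 1 or 3 (adjusted p up to 0.0815, and 0.000183 to 0.164 over all alternatives). MIR3142HG lost the call without NC library 1, 2 or 3 or without OE library 2 or 3 (adjusted p up to 0.0878, and 0.00217 to 0.16 over all alternatives). SNORD14E lies inside HSPA8, itself lower by a log2 change of -0.55, and values of short RNAs inside host genes, SNORD125 and MIR25 included, can contain fragments of the host. RPSA fell from 187 ± 17.1 to 85.2 ± 5.70 FPKM and EEF1B2 from 118 ± 7.13 to 55.3 ± 6.27 FPKM (SD, n = 3). RPL21, RPS3A, RPSA, EEF1B2 and NME1 have processed pseudogenes or a read-through transcript that can share their reads, which FPKM per gene does not resolve.

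Cell cycle genes were lower in OE. KIF20A (-0.76), MCM6 (-0.73), CENPE (-0.51) and CCNB1 (-0.49) fell on the log2 scale. Of 31 tested cell cycle genes, 19 were called lower and 1 higher (20 and 1 adjusted over the list alone), with a median of -0.26 and a camera adjusted p of 1.45e-08 (0.303 with an estimated correlation). In the heat shock list, fixed as cytosolic, HSPA8 (-0.55) and HSP90AA1 (-0.51; not called without a filter, adjusted p = 0.0762) were lower, and so were the mitochondrial chaperonins HSPD1 (-0.55) and HSPE1 (-0.41), which the list also holds. HSPE1 lost its call without OE library 3 (adjusted p = 0.0579, and 0.00591 to 0.0954 over all alternatives). This list had 5 of 12 genes lower and 0 higher (5 and 0 adjusted over the list alone) at a median of -0.17, with a camera adjusted p of 0.0187 (0.303 with an estimated correlation). The heat shock list did not pass after quantile normalization (adjusted p = 0.837) or with a minimum of 5 FPKM (adjusted p = 0.0708), with a range over all alternatives of 0.00907 to 0.837. After quantile normalization 3 of its genes were higher and 4 lower, at a median of -0.014. The mtDNA-encoded transcripts MT-CO3 (-0.94), MT-ATP6 (-0.79), MT-ATP8 (-0.61) and MT-ND3 (-0.61; not called without a filter, adjusted p = 0.0911) were lower, with 7 of 13 called lower and 1 higher (8 and 1 adjusted over the list alone), a median of -0.30 and a camera adjusted p of 0.00132 (0.458 with an estimated correlation).

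In the NF-kB, EMT and landmark m6A lists more genes were called higher than lower. CXCL2 rose from 13.1 ± 0.87 to 27.9 ± 2.20 FPKM (SD, n = 3), CXCL8 by 0.72 log2 units and CXCL3 by 0.81. IL6 rose by 0.54, a call lost without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.105, and 0.00712 to 0.157 over all alternatives). The NF-kB list had 8 of 16 genes higher and 2 lower, the same counts adjusted over the list alone, at a median of 0.29 (camera adjusted p = 0.0187, 0.458 with an estimated correlation). In the EMT and fibrosis list CCN2 (0.88), CCN1 (0.82) and SNAI2 (0.63; not called without a filter, adjusted p = 0.0650) rose, with 13 of 22 higher and 1 lower, the same adjusted over the list alone, a median of 0.32 and a camera adjusted p of 0.00568 (0.458 with an estimated correlation). Among m6A landmark transcripts DUSP6 (0.95) and KLF6 (0.54) rose and EEF2 (-0.45; not called after quantile normalization) fell, while JUNB (0.43) lost its call without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.0941, and 0.0145 to 0.157 over all alternatives). This list had 9 of 23 higher and 1 lower (10 and 2 adjusted over the list alone), a median of 0.16 and a camera adjusted p of 0.0327 (0.531 with an estimated correlation). After centring 6 were higher and 3 lower, at a median of 0.09. It did not pass without NC library 1 (adjusted p = 0.0885, and 0.00107 to 0.0885 over all alternatives). Of the 21 lists tested, 9 passed camera, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. By fry, 18 lists moved, on balance, one way, among them the m6A readers, which hold the overexpressed YTHDF1. But 12 did so after centring and 14 after quantile normalization. With 1 library left out 11 to 16 did so (14 without NC library 1, 12 without NC library 3, 11 without OE library 1).

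**Figure D2:**
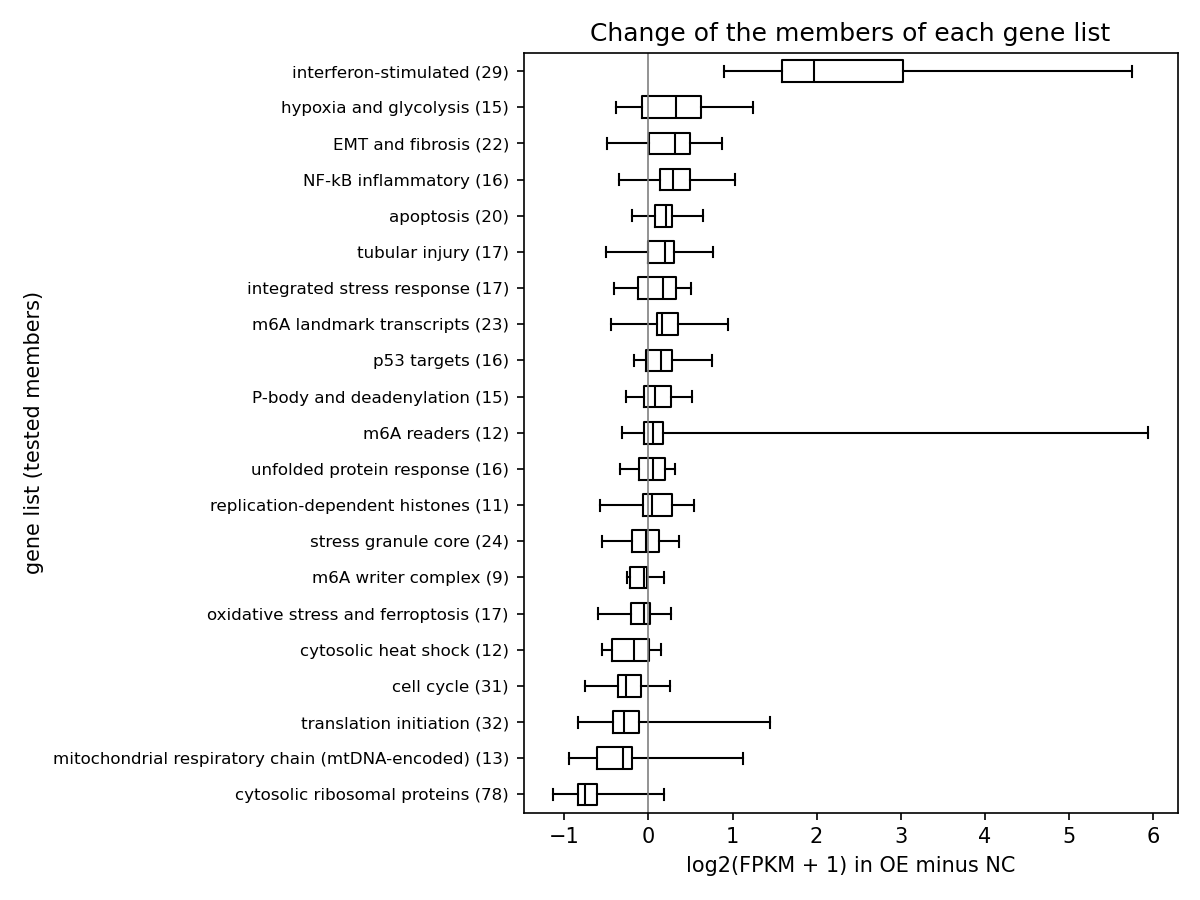
Log2 change of FPKM + 1, OE minus NC, of the tested members of 21 gene lists, sorted by median, with boxes for the quartiles, a line for the median and whiskers to the lowest and highest member. The interferon-stimulated list (29 genes) lies wholly above 0, and the ribosomal protein list (78 genes) has the lowest median.

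Of the m6A machinery, METTL3 was at 6.65 ± 0.43 FPKM in NC and 5.59 ± 0.44 in OE, and METTL14 at 5.01 ± 0.25 and 4.95 ± 0.78 (SD, n = 3). Neither passed. Of the 9 writer genes, VIRMA (-0.25) and ZC3H13 (-0.22) were called lower and 0 higher, also when adjusted over the list alone, but 4 were lower and 0 higher after centring and after quantile normalization. VIRMA lost its call without NC library 1 or OE library 1 or 3 (adjusted p up to 0.0690, and 0.00695 to 0.069 over all alternatives), and ZC3H13 without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.106, and 0.0106 to 0.106 over all alternatives). The eraser ALKBH5 rose from 20.03 ± 1.77 to 25.9 ± 0.66 FPKM (SD, n = 3; adjusted p = 0.00768), and FTO did not pass, so 1 of 2 erasers was higher, also adjusted over the list alone. Of 12 readers 3 were higher, the overexpressed YTHDF1 among them, and 2 lower, also adjusted over the list alone. After centring 1 was higher, which was YTHDF1, and 2 were lower. YTHDF2 and YTHDF3 were not called, and neither the writers nor the readers passed camera (adjusted p = 0.192 and 0.522). HNRNPA2B1 (-0.32) and HNRNPC (-0.30) were lower, but after quantile normalization HNRNPA2B1 changed by 0.011 and HNRNPC was not called (adjusted p = 0.130, and 0.0086 to 0.13 over all alternatives). HNRNPC also lost its call without NC library 1 or OE library 1 or 3 (adjusted p up to 0.0791). IGF2BP2 (0.19) lost its call without any 1 of the libraries but OE library 2 (adjusted p up to 0.0778, and 0.0147 to 0.112 over all alternatives).

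Stress granule components went both ways. HNRNPA1 (-0.55), PABPC1 (-0.48) and DDX3X (-0.37) fell and FXR2 (0.36) rose, and G3BP1 was not called. Of 24 genes of the list, 3 were higher and 7 lower, the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.155). After centring 1 was higher and 11 were lower. Among P-body and deadenylation genes PATL1 (0.41) and EDC4 (0.30) rose, PAN2 (0.52) lost its call without NC library 1 or OE library 3 (adjusted p up to 0.0602, and 0.00417 to 0.103 over all alternatives), and CNOT6 (0.27) without NC library 3 or OE library 3 (adjusted p up to 0.0613, and 0.00658 to 0.0613 over all alternatives). That list had 6 of 15 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.314), and 4 and 3 after centring.

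The integrated stress response, unfolded protein response, tubular injury and p53 lists did not pass camera (adjusted p = 0.279, 0.702, 0.263 and 0.263). The tubular injury list passed after quantile normalization (adjusted p = 0.00304, with a range over all alternatives of 0.00304 to 0.316), though not with an estimated correlation (adjusted p = 0.291). In the integrated stress response DDIT4 (0.51) and PPP1R15A (0.49) rose and PHGDH (-0.38) fell, and VLDLR (0.39) lost its call without OE library 3 (adjusted p = 0.0531, and 0.00396 to 0.0684 over all alternatives). It had 7 of 17 genes higher and 2 lower (8 and 3 adjusted over the list alone), and 6 and 3 after centring. In the unfolded protein response MANF (-0.34) fell and CALR (0.32; not called without a filter, adjusted p = 0.176) rose. EDEM1 (0.28) lost its call without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.0680, and 0.0111 to 0.068 over all alternatives), and PDIA6 (0.23) without NC library 3 or OE library 1 or 3 (adjusted p up to 0.0734, and 0.000785 to 0.0734 over all alternatives). This list had 5 of 16 higher and 2 lower (5 and 3 adjusted over the list alone), but 2 higher and 4 lower after centring and 0 higher and 3 lower without a filter. Among tubular injury genes SOX9 (0.77) and CDKN1A (0.45) rose, ANXA2 (-0.51) fell, and KRT19 (0.31) lost its call without OE library 3 (adjusted p = 0.0572, and 0.00576 to 0.0608 over all alternatives), with 6 of 17 higher and 1 lower (8 and 2 adjusted over the list alone), but 4 and 3 after centring. CDKN1A is also a p53 target, where GDF15 (0.76) rose and TP53INP1 (0.33) lost its call without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.0814, and 0.0178 to 0.0924 over all alternatives). The p53 list had 3 of 16 higher and 0 lower, the same adjusted over the list alone, and 2 and 1 after centring.

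Hypoxia and glycolysis genes CA9 (1.24), ADM (0.81), PFKFB4 (0.72; not called without a filter, adjusted p = 0.0754) and SLC2A1 (0.66) rose, with 7 of 15 genes higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0580). That list passed without NC library 1 (adjusted p = 0.0387), OE library 1 (0.00663) or OE library 3 (0.0370), and after centring (0.0341), quantile normalization (0.00159) or without a filter (0.00907), with a range over all alternatives of 0.00159 to 0.247. With an estimated correlation it passed in none of these (adjusted p = 0.519, 0.500, 0.582, 0.477, 0.484 and 0.385). Apoptosis genes BCL2L1 (0.53) and BAK1 (0.28) rose. BMF (0.64) lost its call without OE library 3 (adjusted p = 0.0539, and 0.00281 to 0.0889 over all alternatives), and MCL1 (0.29) without NC library 1 or 3 or OE library 1 or 3 (adjusted p up to 0.0631, and 0.00568 to 0.0738 over all alternatives). The apoptosis list had 5 of 20 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0580), and passed without NC library 3 (adjusted p = 0.0324), after quantile normalization (0.0276) and without a filter (0.0101), with a range of 0.0101 to 0.145. With an estimated correlation these were 0.382, 0.391 and 0.285. After centring 4 were higher and 2 lower. In the oxidative stress and ferroptosis list TFRC (-0.60), FTL (-0.45) and TXN (-0.42) fell, the last 2 not called after quantile normalization (adjusted p = 0.366 and 0.285, over all alternatives 0.00399 to 0.584 and 0.00253 to 0.285). GCLC (0.27) lost its call without NC library 1 or 3 or any OE library (adjusted p up to 0.112, and 0.0138 to 0.112 over all alternatives). The list had 1 of 17 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.0580), and passed without NC library 1 (0.0224) or OE library 1 (0.0393) and after centring (0.0387), with a range of 0.0224 to 0.759. With an estimated correlation these were 0.267, 0.414 and 0.285. After centring 0 were higher and 6 lower, and after quantile normalization 0 and 1. Replication-dependent histone genes, which poly(A) selection should deplete, had 3 of 11 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.702). H2AC6 (0.54) rose, although not called without a filter (adjusted p = 0.0825), H2BC8 (0.55) lost its call without NC library 1 (adjusted p = 0.0559, and 0.00603 to 0.0851 over all alternatives), H1-2 (0.40) without NC library 2 or 3 or OE library 1 (adjusted p up to 0.0604, and 0.014 to 0.0833 over all alternatives) and H4C12 (-0.57) without any 1 library but NC library 2 (adjusted p up to 0.114, and 0.0228 to 0.199 over all alternatives).

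Of 16 proximal tubule markers only 4 passed the filter, and 2 of these were called higher, also adjusted over the list alone. GGT1 went from 9.55 ± 0.23 to 14.4 ± 1.60 FPKM (SD, n = 3), and ANPEP (0.41) lost its call without NC library 2 or 3 (adjusted p up to 0.103, and 0.0105 to 0.121 over all alternatives). CD68 rose from 22.1 ± 2.01 to 42.3 ± 2.05 FPKM (SD, n = 3) and was the 1 tested leukocyte marker. The fibroblast marker LUM was not called, and of the endothelial and distal nephron markers 0 passed the filter.

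Across 1843 Gene Ontology terms, a search chosen after the data were examined, camera called 89 terms higher and 212 lower, and 0 with an estimated correlation (adjusted p = 0.803 for each term named here, with 37 of all terms at an unadjusted p under 0.05). Beyond the fixed lists, the lowered terms held genes of mitochondria, with 152 of 371 genes of the mitochondrial inner membrane called lower and 14 higher (median -0.22). Of 17 genes of the mitochondrial ATP synthase complex 15 were lower and 0 higher (median -0.51). The raised terms held genes of the extracellular matrix, with 34 of 52 structural constituents higher and 2 lower (median 0.34), and 22 of 39 basement membrane genes higher and 0 lower (median 0.31).

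The third comparison described where m6A lay in each group. In both lists most peaks fell in 3' untranslated regions, where m6A is known to cluster near stop codons. The values are the authors' own. The NC list held 43536 peaks in 15828 genes and the OE list 44620 peaks in 16423 genes. The 3' UTR held 58.1% of NC peaks (95% interval 57.6% to 58.5%) and 57.5% of OE peaks (57.0% to 57.9%). The class exonic held 16.6% and 15.1%, exons of noncoding RNA 11.1% and 12.2%, the 5' UTR 9.96% and 10.7%, and introns 3.95% and 4.20%. The median IP/input ratio was 2.57 in NC and 2.74 in OE.

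Many peaks had an adjusted p listed at 0. Ordered by IP/input among these, the first 5 genes were SENP3, LINC02076, CAPNS1, AC132872 and AP001505 in both lists. The SENP3 peak (chromosome 17, 7561919 to 7562263, 5' UTR) had log2 IP/input of 7.18 in NC and 7.03 in OE. Among landmark transcripts JUN carried a 3' UTR peak (chromosome 1, 58780791 to 58784040) with log2 IP/input of 3.80 in NC and 4.23 in OE, MYC one of 3.03 and 3.18, SOX4 one of 3.07 and 3.32 and CREBBP one of 2.89 and 2.82. The writers RBM15, RBM15B, WTAP and METTL16 had peaks in both groups, RBM15 the strongest at 4.39 in NC and 4.37 in OE. Peaks lay also in the erasers ALKBH5 and FTO, in the readers IGF2BP3 (3.11 in NC, 4.06 in OE), YTHDF2, YTHDF3 and YTHDC1, and in the stress granule genes DDX6 (3.45 in NC, 3.66 in OE), USP10, PUM2, EIF4G1 and TIAL1.

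**Figure D3:**
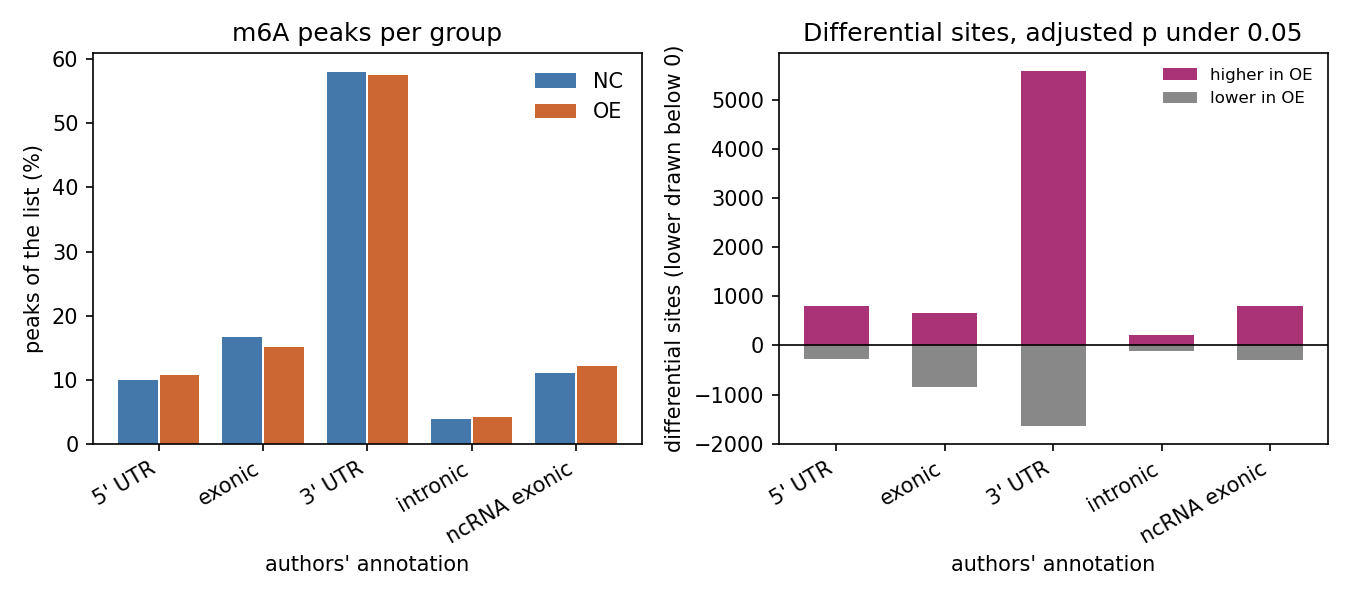
Left, share of the peaks of each group's list (NC blue, OE orange) in the 5 largest classes of the authors' annotation, in percent. Right, number of sites with adjusted p under 0.05 in those classes, higher in OE drawn above 0 and lower in OE below 0, with more sites higher in each class but exonic.

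Of the NC peaks 54.96% overlapped an OE peak by at least 50% of both, and of the OE peaks 53.6% overlapped an NC peak. Any overlap of 1 base was found for 78.8% and 74.9%. By gene, 15259 genes had a peak in both lists, 96.4% of the NC genes and 92.9% of the OE genes. Absence from a list is not a test of a difference. Over 23920 shared pairs, log2 IP/input was higher in OE by a median of 0.071, 60.9% of pairs were higher in OE, and r across pairs was 0.84.

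The fourth comparison asked which sites differed in m6A IP/input between OE and NC. YTHDF1 itself had a site at chromosome 20, 63196279 to 63215958, with log2 IP/input of 3.05 in OE and 1.73 in NC. A site at 63195429 to 63195903 had 2.15 and 1.90. The OE values may be those of RNA from the introduced YTHDF1, so they need not show a change of the cells' own transcript. Both sites were past the threshold in the authors' deposited table. That table held 11283 sites in 8151 genes with an adjusted p under 0.05, 8088 higher and 3195 lower in OE, so that 71.7% were higher (95% interval 70.8% to 72.5%). Sites of the class 3' UTR were higher in 77.3% of cases (5589 against 1642), whereas sites of the class exonic were higher in 43.8% (660 against 846). A site that spans most of a gene still has 1 class, such as the longer YTHDF1 site, classed as 3' UTR. By gene, 5596 had called sites that were only higher, 1650 only lower, and 905 both. The largest differences were at AC044860 (chromosome 15, 85205706 to 85208524; 6.87 log2 units), GPAA1P1 (6.23), ANXA2R (6.11), GPNMB (5.70), VNN2 (5.61), GAS1 (5.54), C13orf46 (5.50), NPIPB9 (5.48), EIF3F (5.37) and SELENOTP1 (5.34). The smallest were at LINC02604 (chromosome 7, 66906082 to 66906281; -5.77), ASGR1 (-5.51), AC023509 (-5.47), STAG3L3 (-5.11), AC010136 (-5.01), AC020659 (-4.58), TCAF1 (-4.50), RAB11B-AS1 (-4.47), FAM110C (-4.40) and AKAP7 (-4.39). Among the largest, log2 IP/input in NC was below 0 at every site but that of GAS1, and among the smallest it was below 0 in OE at AC023509, AC020659 and AKAP7. The depth at these sites is unknown.

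Called sites were common in ribosomal protein genes. Of 77 such genes with a peak, 75 (97.4%) had a called site, against 47.9% of all 17011 genes with a peak (Fisher's exact test, adjusted p = 1.93e-20), and 75 had a site that was higher in OE and 2 a site that was lower. Translation initiation genes had a called site in 27 of 32 (adjusted p = 0.000274; 24 with a higher and 8 with a lower site), cell cycle genes in 24 of 31 (adjusted p = 0.00729; 15 and 11) and landmark transcripts in 19 of 25 (adjusted p = 0.0344; 15 and 8). Histone genes had one in 3 of 19 (adjusted p = 0.0276). Of the interferon-stimulated genes, 15 of 32 had a called site (adjusted p = 1), 12 with a higher site. Stress granule genes had a called site in 15 of 24, m6A readers in 9 of 12, and neither list passed (adjusted p = 0.292 and 0.174). In all, 5 of 22 lists passed. With sites at an unadjusted p under 0.05, the cell cycle, landmark and histone lists no longer passed (adjusted p = 0.130, 0.0814 and 0.0814). Calls of sites can depend on expression, for which the lists were not matched.

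The fifth comparison set the site change against the input change of the same gene. Among the genes with the smallest p-values in the authors' deposited table, HLA-C and IFIT2 were higher in both. So was YTHDF1, with the limit given for its sites. RPL7 (site 0.48, expression -1.04), RPL4 and RPLP0 had higher IP/input and lower expression. HKDC1 and EVPL had lower IP/input and higher expression, and CCNB1, KIF4A and CENPE were lower in both. Across 8269 genes Spearman's rho was -0.080 (95% interval -0.10 to -0.058). Of genes whose largest site change was upward, 51.1% rose in the input, against 65.4% of genes whose largest site change was downward (odds ratio 0.551, Fisher's exact test, p = 8.33e-32). A rise was the sign of the change as deposited, without a threshold, so these shares depend on the scaling. Genes past both thresholds numbered 2398, of which 868 were higher in both, 959 had m6A higher and expression lower, 430 the opposite and 141 were lower in both (odds ratio 0.297). Among these genes rho was -0.146 (95% interval -0.185 to -0.107). Genes are not independent replicates, and both measures contain the input, so that noise in the input alone gives a negative relation.

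**Figure D4:**
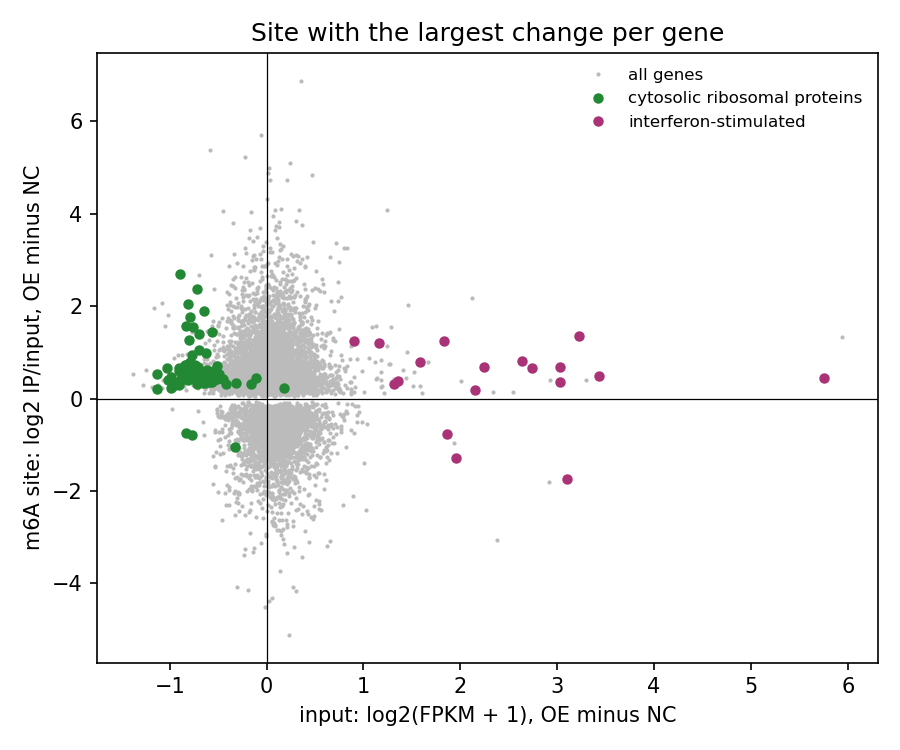
Change of log2 IP/input of the site with the largest absolute difference per gene (vertical axis) against the change of log2(FPKM + 1) in the input (horizontal axis), OE minus NC, for 8269 genes in grey. Ribosomal protein genes (green) lie left of 0 apart from 1 gene, mostly with higher IP/input, and interferon-stimulated genes (purple) lie right of 0.

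The last comparison asked whether transcripts carrying m6A moved with YTHDF1. Genes with a peak in both lists (11554 tested genes) had a median log2 change of 0.045, and genes with a peak in neither (596 genes) one of -0.017. The difference of 0.062 did not pass camera (p = 0.0533, and 0.231 with an estimated correlation). It did pass without NC library 2 (difference 0.072), OE library 1 (0.063), OE library 2 (0.080) or OE library 3 (0.048), though in none of these with an estimated correlation. It did not pass without NC library 1 (0.027) or NC library 3 (0.037). With a minimum of 5 FPKM the difference was 0.220 and passed with both (camera p = 3.24e-06, and 0.0221 with an estimated correlation). By expression, the difference was 0.0015 in the lowest of 10 bins and 0.45 in the highest, where 49 genes without a peak had a median of -0.58 and 1180 genes with peaks one of -0.13 (adjusted p = 0.00317). Bins 7, 8 and 9 passed as well (adjusted p = 0.0107, 0.00840 and 0.00840), bin 8 with only 17 genes without a peak. The bins were tested by camera with the preset correlation alone, so whether they pass with an estimated correlation is unknown. Within bins, genes with and without a peak were not matched for transcript length or gene class. The differences therefore need not come from m6A.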

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

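Most alternatives were chosen before the data were examined; those chosen only after the results were seen were leaving the interferon-stimulated genes out of the marked genes, removing a spline of mean expression, subtracting the median shift of shared peaks, and, before its own values were seen, using called sites only.

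YTHDF1 stayed called under every alternative run, with a log2 change of 5.84 to 6.08 and an adjusted p of 4.65e-09 to 0.00111. The number of genes called between OE and NC, 3958, fell to 2192 without an expression filter, where 29462 genes were tested, and to 642 with a minimum of 1.5-fold. With each input library left out in turn it ranged from 2264 (without OE library 3) to 3836 (without OE library 2), and it was 2534 without NC library 1. With library numbers as a block it was 3074, although the numbers did not pair the libraries. Among the alternatives that tested the same 12438 genes without a fold minimum, the count lay between 3074 and 4941 (array weights). Of the 3958 genes called, 0 changed sign after centring and 7 after quantile normalization. The up and down split moved with the scaling, as given with the counts, which follows from the construction of these settings.

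Of 96 named genes besides YTHDF1, 63 kept their call under every alternative other than the fold minimum, and 42 also under that. The call was lost by 28 genes without a filter, 9 after quantile normalization, 6 after centring, 8 with the block and 1 with array weights, and by 23 genes when at least 1 library was left out. HNRNPA2B1 reversed after quantile normalization, to a log2 change of 0.011 from -0.32 (adjusted p = 0.895); the cause was not tested. Of the 21 tested lists, 15 stayed on their side of the threshold throughout. The number of called lists, 9, lay between 8 and 12. With library numbers as a block, the hypoxia (adjusted p = 0.0433), apoptosis (0.0433) and oxidative stress (0.0471) lists passed camera too (adjusted p = 0.570 for each with an estimated correlation), while 6 lists passed fry in place of 18. With an estimated correlation 0 lists passed in any setting. Of the lists with more genes called higher than lower, the unfolded protein response turned after centring and without a filter. The histones turned without a filter (0 higher, 1 lower). The m6A readers turned after centring, with the block and without NC library 3, with 1 higher, YTHDF1 itself, and 2 lower in each. Array weights and the trend do not enter camera, so they give it no other p.

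The difference between marked and unmarked genes, 0.062, kept its direction under every alternative run. It was 0.220 with a minimum of 5 FPKM, where it passed camera, and 0.027 to 0.080 with each library left out, where it passed in 4 of 6 cases; the cause was not tested. With the preset correlation it did not pass without a filter (0.028), after centring (0.062), without the interferon-stimulated genes (0.061), after removal of a spline of mean expression (0.081) or after quantile normalization (0.069). With an estimated correlation it passed in the last 2 of these and with a minimum of 5 FPKM, and in no other setting.

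The share of peaks in 3' UTRs rose with stricter thresholds, from 58.1% to 59.6% (adjusted p 0.001) and 61.0% (2-fold) in NC and from 57.5% to 58.8% and 60.5% in OE; the cause was not tested. The share of NC peaks found in OE was 78.8% at 1 base, 37.2% at 80% reciprocal overlap, 59.3% for NC peaks past adjusted p 0.001 and 96.4% by gene, and for OE peaks found in NC it was 74.9%, 36.3%, 57.7% and 92.9%. The overlap settings loosen or tighten the criterion itself. Differential sites numbered 6861 at adjusted p 0.01 and 5294 with a minimum of 1.5-fold, fewer by construction. With the median shift of shared peaks subtracted from the called sites, 71.5% were higher in place of 71.7%, which tests little since the higher sites had a median difference of 0.50. The share higher in OE was 75.3% at adjusted p 0.01, 69.3% at unadjusted p 0.05 and 66.0% with a minimum of 1.5-fold; the cause was not tested. At an unadjusted p, 2 lists passed among differential sites in place of 5, with cell cycle, landmark transcripts and histones lost; the cause was not tested. The relation between site and input change stayed negative, with rho of -0.114 for the mean over sites and -0.109 for genes with at least 5 FPKM, and it was strongest, at -0.146, for genes past both thresholds; the cause was not tested.

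Alternatives that needed read counts or values per IP library, and those for the motif, were not run. Depth is unknown, so what it limits at single sites or genes was not assessed.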

Other observations

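Of the tests below, those on the loss of the highest expressed transcripts, library scaling, mRNAs with a 5' TOP tract, a single OE library, leukocytes and other splits of the libraries were chosen only after the results were seen, while those on short transcripts, a uniform shift of IP enrichment and falling input were written before their values were seen, though the last used called sites only, a choice made after other results were seen.

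Ribosomal protein mRNAs were lower in OE, with a median log2 change of -0.75. The tables argue against library scaling as the whole source, because the median stayed at -0.553 or lower after centring and after quantile normalization. Loss of the highest expressed transcripts also has evidence against it as the whole source. The percentile of the ribosomal median was 0.0 among 10000 random lists matched for expression, whose middle 95% ran from -0.24 to -0.087. That range is itself negative, so such a loss stays open as a part. Genes with a peak in both lists had a median change of 0.098 in the lowest expression bin and -0.131 in the highest. Lower measurement of short transcripts stays open, since nuclear-encoded respiratory chain genes fell too (median -0.388, 56 of 77 lower), only just past the bound of -0.377 set for them, and transcript lengths were not checked. A fall of mRNAs with a 5' terminal oligopyrimidine (TOP) tract may be a biological explanation and stays open beside it, since 24 non-ribosomal TOP mRNAs had a median of -0.563 with 20 lower, although some of them were already seen in the translation initiation and stress granule lists.

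Interferon-stimulated genes were higher in OE, with a median log2 change of 1.97. A single OE library does not account for this, as the lowest median with 1 library left out was 1.88. The tables argue against leukocytes in the culture, since the median of 7 leukocyte markers other than CD68 was 0.0268 FPKM in OE, PTPRC among them at 0.0025, and the highest, FCER1G, at 0.90 ± 0.31 in OE, was at 0.73 ± 0.39 in NC (SD, n = 3). An innate response to transfected plasmid DNA and an effect of YTHDF1 itself cannot be separated here, because the labels show no control that received an empty plasmid, and neither was tested.

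More differential m6A sites were higher than lower in OE, 71.7% of 11283. A uniform shift of IP enrichment stays open as a part of this. Over shared peaks, after subtracting the median shift of 0.071, 52.0% of pairs at least 0.5 log2 units away were higher. This lay within the 45% to 55% that such a shift was set to give. Subtracting the median gives a nearly even share for any symmetric spread, with or without a shift, so this test cannot decide. A shift alone would not give the excess of lower sites in the class exonic, where 43.8% were higher, and the called sites were still 71.5% higher after the same subtraction, which can turn few of them at a median difference of 0.50. For falling input of the same genes, the called site with the largest difference per gene was used. Among genes whose input rose, this site was higher in 2541 and lower in 1127. Among genes whose input fell, it was higher in 2560 and lower in 579. Rise and fall here were the sign of the change as deposited, without a threshold, so these counts depend on the scaling. Among genes called higher in the input the counts were 868 and 430, and among those called lower 959 and 141. Of all 3958 called genes, 0 changed sign after centring and 7 after quantile normalization. The excess among genes whose input rose argues against falling input as the whole source. Falling input stays open as a part, since rho across genes with a called site was -0.085 (95% interval -0.11 to -0.062). This relation is weak, and its interval includes the bound of -0.1 set for it. Of the ribosomal protein genes with a peak, 75 of 77 had a site that was higher, and 75 of the 78 tested were called lower in the input. The 2 counts were not matched gene by gene. For this group the site change and the input change cannot be told apart.

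The 6 input libraries allow 10 splits into groups of 3, too few for a share under 0.05. For the count of called genes the real split gave 3958 and the highest other 1, so 1 of 10 splits gave as many. For called lists the real split gave 9 and the highest other 9, and 3 of 10 splits gave as many. For the difference between marked and unmarked genes the real split gave 0.062 and the highest other 0.067, and 2 of 10 gave as large a difference.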
